A study of Homo sapiens with 32 samples.

How the data were processed

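The series holds 32 samples of primary human keratinocytes from a mixture of multiple donors. RNA-seq covers 18 libraries: PBRM1 knockdown with 3 hairpins and PIAS1 knockdown with 2 hairpins, each against 2 control hairpins (A, non-targeting, and B, against GFP), undifferentiated and after 4 days in 1.2 mM calcium chloride, with selection in puromycin at 2 µg/mL for 48 h. ChIP-seq covers 8 libraries (PBRM1 and PIAS1, 2 replicates per state, with a different catalogue form of the PBRM1 antibody in each replicate) and CUT&RUN 6 libraries. Values exist for 28 samples. The BRD7 libraries of PBRM1 knockdown cells (3) and the IgG library (1) are not analysed here. Groups and replicate letters or numbers follow the labels.

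The deposited notes of the submitters name Trim Galore, FastQC, STAR, Salmon, DESeq2, BWA, bedtools, edgeR, DiffBind and MACS2 and the genome build hg38; the role and version of each are not given in the sources used here. The RNA tables deposited by the authors give normalised signal (normalised counts) for 26475 genes per library. These are read counts divided by 1 size factor per library, since whole reads were recovered within a tolerance of 0.01 from all values of every library. Per the file headers the tables also hold the authors' log2 fold change with its standard error, and their p-value and adjusted p-value in the form DESeq2 writes. The deposited peak lists give −log10 q per region in their last column, while the other score columns hold impossible values and were not used. The lists were called per library, and the cutoff of 0.001 stands in a file name only. The lowest −log10 q in a list was 0.0676 to 0.433, and 1.60 and 1.39 for PIAS1 in differentiated cells. The lists thus hold regions that do not pass a q of 0.001. Library depth was 13.4 M to 42.7 M recovered reads. In the PIAS1 table of undifferentiated cells 28 entries with names turned into dates were left out. Knockdown replicate 3 of PBRM1 in differentiated cells was left out of the count tests because its size factor is close to 1. Its values also gave whole reads within the tolerance. The count tests of PBRM1 in differentiated cells thus have 1 knockdown library fewer.

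Fixed before the data were examined were the groups, the comparisons, 23 gene lists, the rule for named genes and most alternatives. Each knockdown was compared with its controls by limma-trend (limma 3.58.1, R 4.3.3) on log2 of the normalised count plus 1, for genes with a mean of at least 10, with Benjamini-Hochberg adjustment and a threshold of 0.05; tests are two-sided. The lists are cornified envelope, spinous keratins and adhesion, barrier lipid and protease, differentiation transcription factors, basal progenitor, proliferation, DNA replication, interferon response, cytokine and NF-kB response, hyperproliferation and wound keratins, simple and mucosal keratins, p53 targets, TGF-beta and EMT, SWI/SNF subunits, SUMO pathway, cholesterol biosynthesis, glycolysis and hypoxia, immediate early and heat shock, mitochondrially encoded (0 of its 15 members are in the tables, so it gives no result), and markers of fibroblasts, melanocytes, immune and Langerhans cells and endothelium. Of the fibroblast markers 17 of 17 are in the tables, of the melanocyte markers 12 of 12, and 10 to 12 and 4 to 8 were expressed enough to be tested. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry.

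The difference of a knockdown effect between states is the difference of the log2 changes over the root of the summed squared SE, against a normal reference and, chosen later, a t reference. Lists were tested on it with camera on the ranked differences and, chosen later, with an estimated correlation in a single edgeR fit of both states, without and with the hairpin as a block. Shared calls were tested with Fisher's exact test. The controls were compared between states with edgeR 4.0.16 (quasi-likelihood, TMM) on recovered reads, and the direction of each series' calls was set against the controls of the other series. Genes listed at 0 in a group are given against a floor of 3 reads per library, and those with 1 to 3 reads as a ratio with a 95% counting interval.

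Named genes are, per comparison, both targets, up to 6 largest rises and 6 largest falls among called genes with a mean of at least 50 whose knockdown libraries all lie beyond both controls, up to 3 called members per list by size of change, or the member with the highest mean where none was called, and the 6 largest changes called in both knockdowns. For regions they are the 3 with the highest score per protein and state and those near named genes. The rule asked for fold enrichment; the −log10 q of the lower replicate took its place. Genes with near-identical copies are named with that limit. A few results that the rule selects are not reported.

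Regions found in both replicates share at least 1 bp. Overlaps were compared with 100 shuffles of position, with and without keeping the distance class to gene ends (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, bedtools 2.31.1). Positions are in hg38, counted from 1. The gene table gives no strand, so a region counts as near a gene within 5 kb of either end of the gene in place of its start; 98.1% of tested genes had a position. Genes with a region were compared by Fisher's exact test and within 4 quartiles of expression. Figures were drawn with matplotlib 3.10.9.

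Hairpins with the same label were checked as pairs across states (the PIAS1 columns carry letters in one state and numbers in the other, and whether these are the same hairpins is not stated): their deviations from the group mean correlated at 0.583, 0.62 and 0.42 for PBRM1 and 0.569 for PIAS1, while the controls gave −0.0939 and −0.0513. The libraries within a state are not paired.

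The tests were run on simulated data with the same group sizes and 1 spread per gene shared by controls and knockdowns. The real undifferentiated controls lay closer together than the knockdowns. Their chi-square of read counts per degree of freedom was 7.29 against 120 to 158 for PBRM1, and 16.2 against 292 for PIAS1. The rates below thus come from a simpler setting than the data. Of genes changed by 1, 2 and 4 on the log2 scale, limma found 19.8, 85.5 and 98.4% in the design of PBRM1 in undifferentiated cells, 0, 54.3 and 92.2% in that of PBRM1 in differentiated cells, 3.45, 58.7 and 98.5% for PIAS1 undifferentiated and 4.76, 57.1 and 100% for PIAS1 differentiated, with 3 to 9 false calls. With no simulated difference between states the normal form called 8 and 13 genes and the t form 3 and 0. Of 200 random sets of regions 5% passed the overlap test.

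Alternatives tried were the authors' deposited adjusted p, edgeR on recovered reads, quantile scaling, the same total per library, no filter and a mean of at least 100, pseudocounts of 0.1 and 10, an added log2 threshold of 1, an adjusted p of 0.01, replicate blocks, leaving out each library, other region thresholds, distances of 1 and 50 kb and a reciprocal overlap of 50%. Of these edgeR on recovered reads, the same total, the t form and the distance to gene ends were chosen after the data were seen.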

Results

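Primary human keratinocytes, a mixture from multiple donors, were kept undifferentiated or were differentiated for 4 days in 1.2 mM calcium chloride. PBRM1, a subunit of the PBAF form of the SWI/SNF chromatin remodeller, or PIAS1, a SUMO E3 ligase, was knocked down with lentiviral hairpins, and RNA was sequenced from 18 libraries. Occupancy of PBRM1 and PIAS1 was mapped by ChIP-seq in both states, and that of BRD7, another PBAF subunit, by CUT&RUN in undifferentiated control cells. The comparisons ask which genes change when each protein is reduced, whether this differs between the states, and where the proteins lie on the genome. The labels do not say that replicates are separate cultures, so p-values of limma, edgeR and fry measure only the spread between these libraries. Fisher's exact tests and camera compare genes, which are not independent replicates, and the shuffles compare region positions. Intervals on ratios and floors cover counting error only.

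Differentiation changed 9654 of 13971 genes in the 8 control libraries (edgeR, 4915 higher and 4739 lower). All 46 tested cornified envelope genes, which build the protein shell of the outermost cells, rose (median log2 7.25), and so did all 34 genes for barrier lipids and proteases (6.14). FLG rose by 6.95, IVL by 4.35 and the spinous keratin KRT1 by 6.30 on the log2 scale. MKI67, a proliferation marker, changed by −2.97, and 34 of 39 DNA replication genes and 22 of 34 proliferation genes fell. Of 30 basal progenitor genes, 22 fell and 5 rose. PBRM1 itself fell (log2 −1.02, 52.4 ± 1.92 to 26.1 ± 4.50 CPM, mean ± SD, n = 4 each, edgeR adjusted p = 7.9e-05). BRD7 (−0.74, adjusted p = 0.000298) and ARID2 (−0.78, 0.000241), which are also PBAF subunits, fell as well, as did 18 of 25 SWI/SNF genes, while PIAS1 rose (0.52, 0.0102). Apart from the targets, the genes named for this contrast were chosen after their values were seen. The states come from separate tables, so state and table cannot be told apart in this contrast.

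In undifferentiated cells with PBRM1 knockdown, PBRM1 itself fell from 1849 ± 71.0 to 335 ± 133 normalised counts (mean ± SD, n = 2 controls and 3 knockdowns). That is a log2 change of −2.55 ± 0.37 (SE, limma adjusted p = 0.0346), with all 3 knockdown libraries below both controls. PIAS1 did not pass the test (0.15, adjusted p = 0.624). Of 14019 genes tested, 360 rose and 74 fell. The rises were led by KRT23, a keratin of differentiating cells (6.07 ± 0.36, adjusted p = 0.00781, 50.7 to 3216 counts), the calcium-binding S100P (5.65 ± 0.52, 0.0126) and the ubiquitin ligase gene RNF222 (5.37 ± 0.65, 0.0227). EEF1A2, a translation elongation factor, had 3 reads over both controls, and its ratio was 117 (95% counting interval 39.7 to 568). The falls were led by the tight junction gene CLDN11 (−5.14 ± 0.92, 0.0469), the secreted peptide gene APLN (−3.18 ± 0.42, 0.0277), DENND2A (−2.76 ± 0.43, 0.0393), the vesicle protein gene SV2A (−2.76 ± 0.49, 0.0464) and CNTNAP1 (−2.45 ± 0.43, 0.0463). Every gene named as rising or falling lay on one side of both controls in all 3 knockdown libraries.

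**Figure D1:**
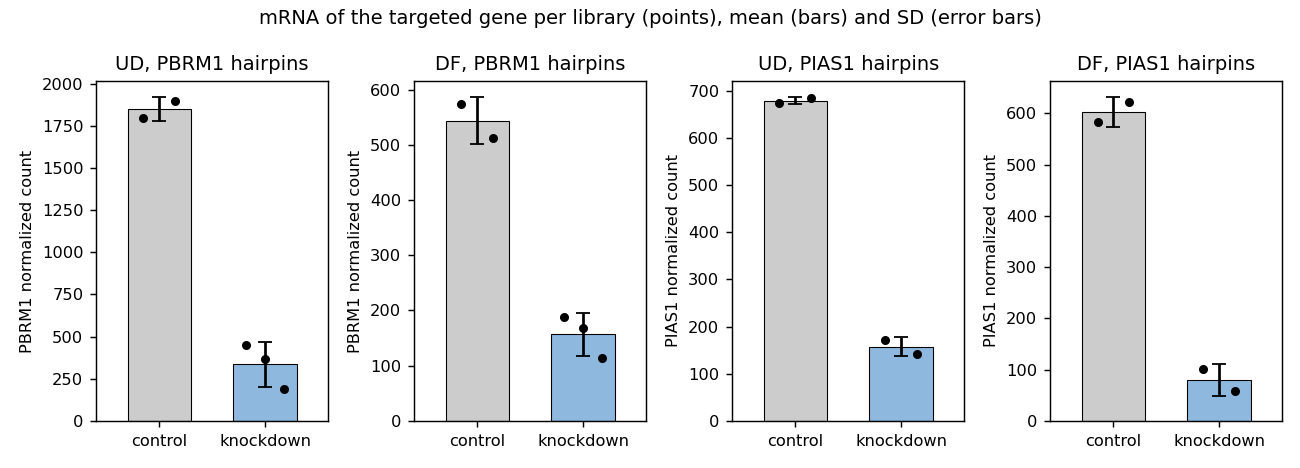
Normalised counts of the targeted gene in control and knockdown libraries of the 4 comparisons; points are libraries, bars means and error bars SD. The targeted gene lies below both controls in every knockdown library.

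A pair of the largest rises belong to genes with near-identical copies. RGPD8 was listed at 0 in both controls and was at least 173-fold higher in knockdown (floor of 3 reads per library), but the sum over RGPD5, RGPD6 and RGPD8 rose by 1.23 on the log2 scale. HIST2H2AA4 was at least 92.8-fold higher, and its sum with HIST2H2AA3 rose by 1.38.

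Genes of epidermal differentiation were among those that rose after PBRM1 loss. Of 44 tested cornified envelope genes, all had a positive change, 24 rose and 20 were not called (37 higher adjusted over the list alone). Their median was 4.39 and the camera adjusted p was 1.3e-26 (adjusted p = 0.332 with an estimated correlation). Among them were KRTDAP (5.36 ± 0.38, limma adjusted p = 0.00781, 98.2 to 4087 counts), LCE2B (5.22 ± 0.94, 0.0473) and SPRR2G (5.10 ± 0.57, 0.0204), of which LCE2B and SPRR2G have close family members. Spinous keratin and adhesion genes showed 13 rises in 27 (22 adjusted over the list alone, median 2.62, camera 1.1e-13, 0.332 estimated), with KRT78 (4.96 ± 0.55, 0.0203) and the desmosomal cadherin DSC1 (4.66 ± 0.84, 0.0475). Barrier lipid and protease genes showed 11 rises in 33 (28 over the list alone, median 3.65, 5.0e-17, 0.332 estimated). They include the retinol dehydrogenase relative SDR9C7 (5.15 ± 0.48, 0.0126), the lipoxygenase ALOX12B (5.03 ± 0.82, 0.0427) and ARG1, with 3 control reads and a ratio of 44.7 (15.1 to 219). Differentiation transcription factors showed 9 rises in 30 (22 over the list alone, median 2.07, 6.3e-12, 0.332 estimated). OVOL1, a zinc finger repressor of progenitor genes, rose by 5.27 ± 0.42 (adjusted p = 0.00905, 54.8 ± 6.41 to 2328 ± 1079 counts), ZNF750 by 4.76 ± 0.44 (0.0126) and the grainyhead factor GRHL1 by 3.93 ± 0.44 (0.0203).

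Of 30 basal progenitor genes, 3 fell and 27 were not called: the Notch ligand DLL1 (−2.11 ± 0.18, adjusted p = 0.0101, 799 to 184 counts), LRIG1, which restrains EGF receptor signalling in stem cells (−1.18 ± 0.17, 0.0359), and PDPN (−1.14 ± 0.18, 0.0401). The same number fell adjusted over the list alone, with a median of −0.27 (camera 0.0354, 0.446 estimated), and the camera call was lost without knockdown replicate 1 or 3. Proliferation and replication genes moved down together, though no member passed over all genes by limma or edgeR. Neither list passed fry (adjusted p = 0.144 and 0.170). Of 34 proliferation genes all were negative, with 31 lower at an unadjusted limma p under 0.05 and 30 adjusted over the list alone (median −1.21, camera 2.4e-13, 0.444 estimated; 22 lower in the authors' deposited table). Of 39 replication genes 38 were negative, with 30 lower unadjusted and 18 adjusted over the list alone (median −1.06, 4.0e-12, 0.444 estimated; 18 in the authors' deposited table). MKI67 changed by −1.02 ± 0.55 (0.302) and the helicase subunit MCM7 by −1.31 ± 0.34 (0.0930, called in the authors' deposited table).

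**Figure D2:**
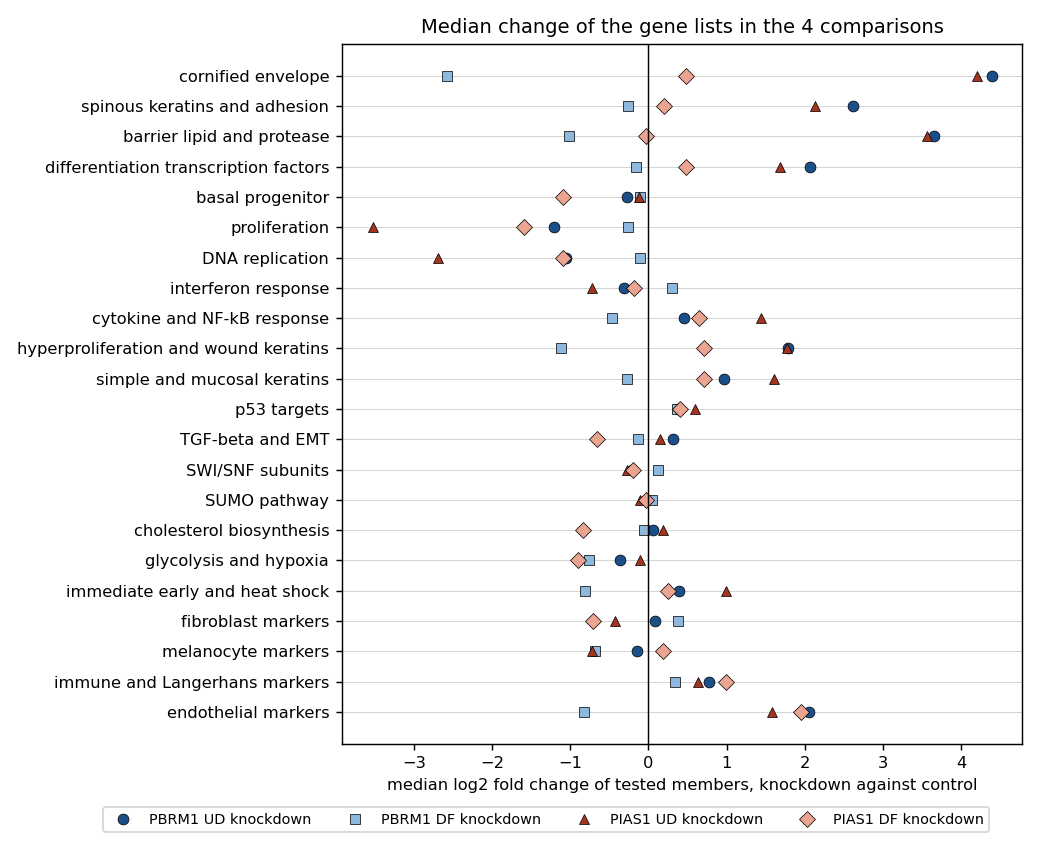
Median log2 change (knockdown against control) of the tested members of each gene list, 1 point per list and comparison. Cornified envelope genes have medians of 4.39 and 4.20 in undifferentiated cells with PBRM1 and PIAS1 knockdown, and −2.58 and 0.49 in differentiated cells.

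Stress and inflammation lists moved less. Hyperproliferation and wound keratins showed 2 rises in 6 (5 adjusted over the list alone, median 1.79, camera 0.00024, 0.332 estimated), KRT16 (3.26 ± 0.47, limma adjusted p = 0.0342) and KRT6B (2.47, 0.0427), which has close copies. Cytokine and NF-kB genes showed 3 rises in 38 (6 over the list alone, median 0.46, camera 0.0354, 0.562 estimated, lost without knockdown replicate 1): PI3 (3.48, 0.0173), S100A9 (3.36 ± 0.27, 0.00905) and S100A8 (2.78, 0.0143). Immediate early and heat shock genes had 2 rises in 28, EGR3 (5.07, 0.0223) and CHAC1 (2.06, 0.0168), with 10 higher and 2 lower over the list alone (median 0.39, camera 0.0178, 0.332 estimated, lost without knockdown replicate 2). The p53 targets TP53INP1 (1.79) and SESN2 (1.17) rose among 28 (5 over the list alone, median 0.38, camera 0.00381, 0.444 estimated, lost without knockdown replicate 2). Interferon genes showed 1 rise, GBP2 (2.84), and 1 fall, HERC5 (−1.41), in 47 (1 higher and 2 lower over the list alone, median −0.31, camera 0.0381, 0.444 estimated). That camera call was lost with libraries scaled to the same total (0.0505) and without control A or knockdown replicate 1 or 2. TGF-beta and EMT genes showed 2 rises in 26, ID2 (3.52) and ITGA5 (0.71), with 2 over the list alone (median 0.31, camera 0.0653, 0.444 estimated; 0.0477 at the same total, and also called without knockdown replicate 3).

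PBRM1 was the only called gene of 24 SWI/SNF subunits (1 over the list alone, median −0.21, camera 0.0468, 0.571 estimated, lost without control A or knockdown replicate 3). Of 30 cholesterol genes 1 fell (1 higher and 1 lower over the list alone), with a median of 0.05 (−0.01 at the same total, −0.07 without knockdown replicate 3, camera 0.984). Among 24 glycolysis and hypoxia genes 2 were higher and 1 lower adjusted over the list alone (median −0.37, camera 0.0403, 0.444 estimated, lost without control A or knockdown replicate 1); GAPDH changed by −0.64 (0.173). The SUMO pathway genes had a median of −0.03 in 24 (camera 0.865), among them RANBP2 (0.32, not called), and the simple and mucosal keratins 0.97 in 7 (camera 0.301, called without knockdown replicate 2), among them KRT19 (0.97, 0.259). Markers of other cell types gave COL1A1 (2.15) and COL5A2 (−1.94) among 10 fibroblast genes (median 0.09, −0.17 without knockdown replicate 3, mean −0.09, camera 0.986), CD68 (1.18) among 2 immune genes (median 0.78, camera 0.123), TYRP1 (−0.95, not called) among 8 melanocyte genes (median −0.14, 0.27 without knockdown replicate 2, camera 0.866) and EGFL7 (0.80, limma 0.104, called in the authors' deposited table) among 2 endothelial genes (median 2.05, camera 0.0381, 0.332 estimated, lost without knockdown replicate 2). Of 22 lists, camera called 9 upward and 6 downward with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.332. The fry test called 7: cornified envelope, spinous, barrier, transcription factors, wound keratins, immediate early and endothelial genes.

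The count of genes after PBRM1 loss rests on few libraries. It was 3 without control A (KRT23, RGPD8, RRAD), 8 without control B (ASPRV1, CDSN, FLG, HMOX1, KRT23, KRTDAP, RGPD8, RRAD), 452 without knockdown replicate 1, 1793 without replicate 2 and 64 without replicate 3 (RRAD chosen after its values were seen). Without control A or B the call on PBRM1 ended too, and of the other named genes only those listed were called. Without replicate 1 the calls of RNF222, APLN, SV2A, LCE2B, DSC1, ALOX12B, PDPN, GBP2, KRT16, KRT6B, TP53INP1, ID2, EGR3 and CD68 ended, and without replicate 2 that of CLDN11, while KRT19 and GAPDH were then called. Without replicate 3, of the named genes PBRM1, RGPD8, HIST2H2AA4, KRT23, EEF1A2, S100P, KRTDAP, SPRR2G, SDR9C7, OVOL1, DLL1, PI3 and S100A9 were still called. The edgeR test on recovered reads gave 212 higher and 35 lower, and ended the calls of CLDN11, SV2A, CNTNAP1, LCE2B, DSC1, ALOX12B, GBP2, KRT6B, TP53INP1, SESN2 and ITGA5. Scaling to the same total ended those of TP53INP1 and ITGA5, and quantile scaling those of CLDN11, LCE2B, DSC1, GBP2 and ITGA5. Without the filter on low values CLDN11, SV2A, CNTNAP1, LCE2B, DSC1, KRT6B and ITGA5 were not called, with a mean of at least 100 CLDN11, CNTNAP1 and LCE2B were not, with a pseudocount of 10 LCE2B, DSC1 and ALOX12B were not, and with 0.1 CLDN11 was not. The authors' deposited table calls 1496 higher and 790 lower.

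In undifferentiated cells with PIAS1 knockdown, PIAS1 fell from 679 ± 6.97 to 157 ± 20.2 normalised counts (mean ± SD, n = 2 each), a log2 change of −2.11 ± 0.25 (limma adjusted p = 0.0325), below both controls in both knockdown libraries. PBRM1 did not pass the test (0.24 ± 0.26, 0.548); its change was −0.11 with libraries scaled to the same total, −0.06 without knockdown A, and 0.54 and called without knockdown B. Of 13794 genes, 718 rose and 401 fell, and the named ones lay beyond both controls in both knockdown libraries. The rises were led by ELF3, an epithelial ETS factor (7.85 ± 1.02, 0.0331, 13.8 to 4795 counts), the glucose transporter gene SLC5A1 (7.71 ± 0.97, 0.0329) and the secreted phospholipase PLA2G2F (7.47 ± 0.96, 0.0331). The ubiquitin ligase TRIM63 had 2 control reads and a ratio of 453 (95% counting interval 125 to 3747). The falls were led by the kinesin gene KIF18B (−4.10 ± 0.65, 0.0398), HJURP, which loads centromeric histone (−3.96 ± 0.69, 0.0450), NUF2 of the kinetochore (−3.72 ± 0.71, 0.0497), RAD54L (−3.66 ± 0.65, 0.0461) and XRCC2 (−3.60 ± 0.68, 0.0487) of homologous recombination, and the RNA-binding ELAVL2 (−3.71 ± 0.49, 0.0343). PLA2G4B and HIST2H2AA4 were listed at 0 in both controls and were at least 679-fold and 184-fold higher. PLA2G4B overlaps JMJD7, and their sum rose by 3.09; HIST2H2AA4 with its copy rose by 2.19.

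Proliferation and replication genes fell widely after PIAS1 loss. Of 34 proliferation genes 10 fell and 24 were not called, and all 34 were lower adjusted over the list alone (median −3.52, camera adjusted p = 2.1e-15, 0.495 with an estimated correlation). NUF2, CDCA3 (−3.28, limma 0.0377) and the mitotic kinesin KIF11 (−3.21 ± 0.49, 0.0385) are examples. Of 39 replication genes 27 fell and 12 were not called, with 38 adjusted over the list alone (median −2.69, camera 6.8e-19, 0.495 estimated), led by GINS2 (−3.36 ± 0.48, 0.0360), the licensing factor CDC6 (−3.35, 0.0439) and ORC1 (−3.18, 0.0383).

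Differentiation genes were among those that rose, as after PBRM1 loss, though most members of each list were not called. Cornified envelope genes showed 10 rises in 44 (39 adjusted over the list alone, median 4.20, camera 2.8e-14, 0.495 estimated; 42 higher in the authors' deposited table), with SPRR2A (5.67 ± 0.60, limma 0.0319), SPRR2D (5.04 ± 0.63, 0.0329) and CNFN (5.03 ± 0.93, 0.0475). SPRR2A and SPRR2D share sequence with each other. Spinous genes showed 10 rises in 25 (13 over the list alone, median 2.13, 8.0e-07, 0.495 estimated), led by the Notch receptor NOTCH3 (5.43 ± 0.32, 0.0243, 111 ± 11.7 to 5013 ± 1844 counts), CLDN4 (5.18 ± 0.59, 0.0325) and SULT2B1 (5.17, 0.0344). Barrier genes showed 10 rises in 34 (21 over the list alone, median 3.56, or 3.47 with 3 members of an all-zero group at their bound, 7.0e-11, 0.501 estimated), among them the kallikreins KLK6 (6.26 ± 0.45, 0.0301) and KLK7 (5.60 ± 0.53, 0.0319) and TMPRSS11E (5.86 ± 0.85, 0.0370). Of 29 transcription factors 11 rose (16 over the list alone, median 1.68, 7.2e-08, 0.495 estimated), with ELF3, OVOL1 (6.41 ± 0.72, 0.0325, 59.2 to 5088 counts) and ZNF750 (5.23 ± 0.83, 0.0397). Basal progenitor genes went both ways: 2 rose, WNT10A (3.05, 0.0439) and the stem cell keratin KRT15 (2.86 ± 0.37, 0.0331), and 3 of 30 fell, among them PDPN (−1.94 ± 0.35, 0.0467), with 3 higher and 8 lower over the list alone (median −0.12, camera 0.441).

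**Figure D3:**
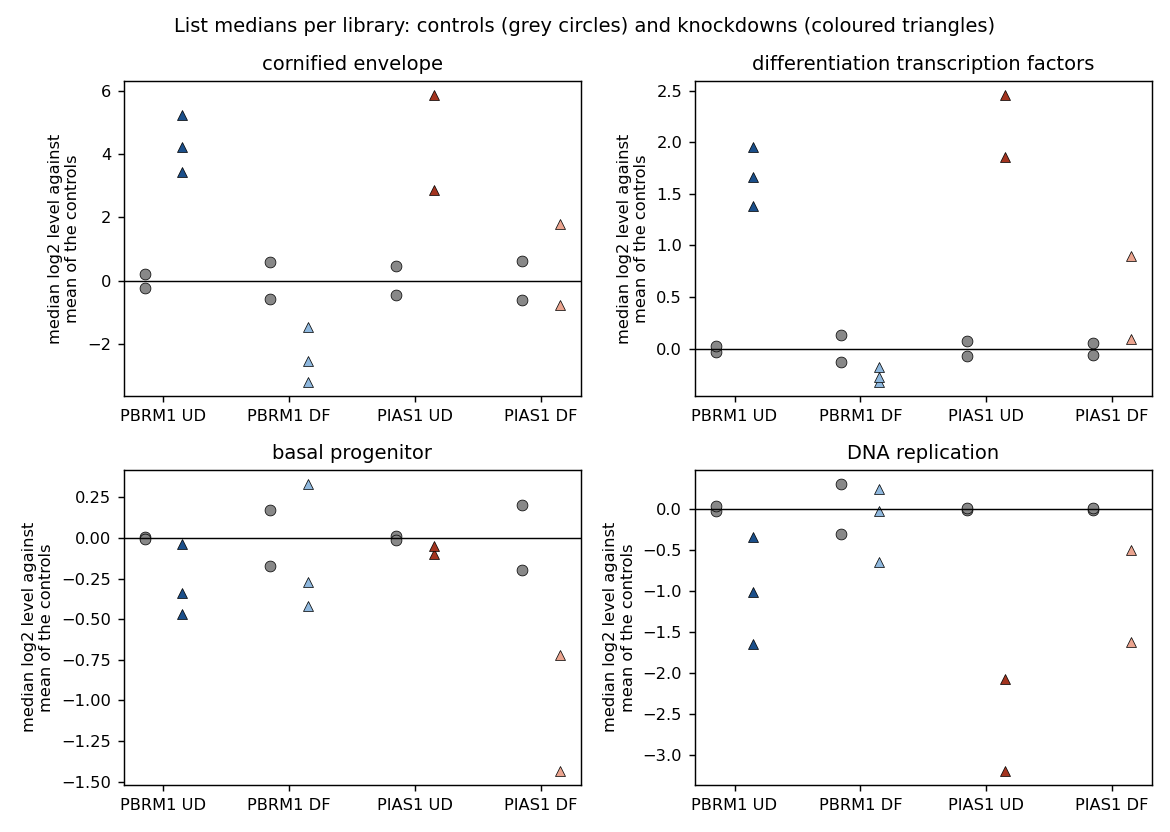
Median log2 value of a gene list in each library against the mean of the controls of its table, 1 point per library. Cornified envelope medians are 3.43 to 5.26 in the undifferentiated PBRM1 knockdown libraries, and −0.77 and 1.80 in the differentiated PIAS1 knockdown libraries.

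Some keratins and stress genes also rose after PIAS1 loss. The p53 targets had 8 rises and 1 fall in 28 (13 higher and 1 lower adjusted over the list alone, median 0.60, camera 0.00129, 0.495 estimated, lost without knockdown A). The cell cycle inhibitor CDKN1A rose by 2.94 ± 0.24 (limma 0.0301, 10281 to 80233 counts), with SESN2 (2.06) and TP53INP1 (1.87). Wound keratins showed 3 rises in 6 (4 over the list alone, median 1.78, camera 0.00316, 0.495 estimated): KRT16 (3.22 ± 0.42, 0.0331), KRT6B (2.49) and KRT17 (1.46). Simple keratins showed 3 in 7 (5 over the list alone, median 1.61, camera 0.00134, 0.495 estimated): KRT19 (2.74), KRT8 (1.61 ± 0.17, 0.0323) and KRT18 (1.20). Cytokine genes showed 8 in 40 (14 higher and 1 lower over the list alone, median 1.44, camera 5.6e-05, 0.495 estimated), with S100A9 (5.58 ± 0.73, 0.0331), LIF (4.50) and DEFB4A, which has near-identical copies, 2 control reads and a ratio of 38.2 (10.2 to 322). Immediate early genes showed 6 in 27 (12 higher and 2 lower over the list alone, median 0.99, camera 0.0139, 0.495 estimated, lost without knockdown A), with EGR3 (5.60), CHAC1 (2.81) and JUNB (2.15). Interferon genes tended down (median −0.72 in 44, camera 0.00136, 0.675 estimated, lost without knockdown B), while ISG20 (2.65) and RSAD2 (2.32) rose (1 higher over the list alone).

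Other lists did not pass camera. TGF-beta and EMT genes had 5 rises and 1 fall in 28 (5 higher and 2 lower over the list alone), with the matrix metalloproteinases MMP10 (3.83), MMP1 (3.12) and MMP9 (2.91); their median of 0.15 was −0.20 at the same total (camera 0.444). Among 30 cholesterol genes 3 rose, MSMO1 (1.63) and SC5D (1.12) among them, with 9 higher and 2 lower over the list alone and a median of 0.19 (−0.16 at the same total, camera 0.371). HK2 (1.19) and SLC2A1 (0.86) rose among 24 glycolysis genes (2 over the list alone, median −0.11, camera 0.845). SWI/SNF subunits had a median of −0.27 in 25 (camera 0.0831, but 0.0414 at the same total), among them SMARCA4 (0.46, limma 0.464; called without knockdown A, −0.10 without knockdown B), and the SUMO pathway −0.11 in 24 (0.03 without knockdown A, camera 0.884), where PIAS1 was the only call. Of 12 fibroblast genes S100A4 (3.24) and COL6A1 (1.89) rose (median −0.42, mean 0.43, camera upward, 0.845), and CD68 (1.67) rose among 2 immune genes (median 0.63, camera 0.462). Melanocyte genes had a median of −0.73 in 7 (TYRP1 −0.75, camera 0.599) and endothelial genes of 1.58 in 3 (EGFL7 0.27, −0.09 at the same total, camera 0.314). Camera called 9 lists upward and 3 downward; with an estimated correlation it called 0, with a lowest adjusted p of 0.495, and fry called 0.

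The PIAS1 calls needed both controls: without control A or B limma called 0 genes, while it called 7427 without knockdown A and 5945 without knockdown B. The split between rises and falls depends on the scaling, with 514 higher and 1251 lower at the same total per library and 791 and 770 under quantile scaling. At the same total the median of all genes moved by −0.36. The edgeR test gave 539 higher and 305 lower, and the authors' deposited table gives 1907 and 1301. The edgeR test ended the calls of PLA2G4B, HJURP, NUF2, RAD54L, XRCC2, CNFN, WNT10A, PDPN, CDC6, RSAD2, KRT6B, MMP9, MSMO1, SC5D, SLC2A1, EGR3 and CD68. Scaling to the same total ended those of KRT6B, MMP9, MSMO1, SC5D, HK2, SLC2A1 and CD68, quantile scaling those of KRT6B, KRT17, KRT18, MMP9, MSMO1 and SLC2A1, and a pseudocount of 10 that of PLA2G4B. With a pseudocount of 0.1 NUF2, XRCC2, DEFB4A and MMP9 were not called, without the filter on low values XRCC2, KRT17 and SLC2A1 were not, and with a mean of at least 100 XRCC2 was not.

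The knockdowns of PBRM1 and PIAS1 shared many genes in undifferentiated cells. Of 13514 genes tested in both, 142 rose in both (18.4 expected, Fisher's exact test odds ratio 15.1, p = 2.2e-91), 24 fell in both (2.19 expected, 16.7, p = 4.7e-19) and 0 were called in opposite directions. The shared rises are 40.5% of the PBRM1 rises, and the shared falls 32.4% of the PBRM1 falls. Among the largest shared rises were OVOL1 (5.27 and 6.41 after PBRM1 and PIAS1 loss), the autophagy gene ATG9B (4.41 and 7.21), the protease gene TMPRSS11F (4.91 and 6.20) and the nectin gene PVRL4 (4.99 and 5.92). HIST2H2AA4 rose in both too, but was listed at 0 in both controls of each series, so the size of its rise is not known. Among the fixed lists they included 7 spinous genes, 5 transcription factors, 4 cornified envelope genes and 2 wound keratins, and the shared falls included 2 basal progenitor genes. Across genes, which are not independent replicates, the log2 changes had Spearman's rho 0.706 and Pearson's r 0.771. The count of 166 shared calls was 1 without PBRM1 control A, 2 without its control B, 24 without its knockdown replicate 3 and 546 without replicate 2; it was 0 without either PIAS1 control, 390 without PIAS1 knockdown A and 334 without knockdown B. The authors' deposited tables share 948 rises and 452 falls.

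These changes mostly went the way of differentiation. Of 331 genes called after PBRM1 knockdown and between the states in the controls of the PIAS1 series, 297 (89.7%) moved in the direction of differentiation (Fisher's exact test odds ratio 30.4, p = 2.6e-20). After PIAS1 knockdown, against the controls of the PBRM1 series, 814 of 888 (91.7%) did (Fisher's exact test p = 1.2e-141).

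In differentiated cells with PBRM1 knockdown, PBRM1 went from 543 ± 42.8 to 157 ± 39.0 normalised counts (mean ± SD, n = 2 controls and 3 knockdowns), with all 3 knockdowns below both controls. Its log2 change of −1.82 ± 0.33 did not pass (limma adjusted p = 0.759), whereas the authors' deposited table gives −1.79 with an adjusted p of 0.000899. PIAS1 changed by 0.55 (0.897). No gene of 14080 passed limma (lowest adjusted p 0.0594) or edgeR, and none passed limma with any 1 knockdown library left out. At an unadjusted p under 0.05 limma gave 271 higher and 445 lower, near the number that chance gives, and edgeR gave 1193. Scaled to the same total, HIST2H2AA3 passed (adjusted p = 0.0495, chosen after its values were seen); it was listed at 0 in both controls, the sum with its near-identical copy changed by −0.32 before that scaling, and the median of all genes moved by 0.14. The authors' deposited table calls 16 higher and 65 lower.

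Cornified envelope genes nevertheless went down as a group, opposite to their rise in undifferentiated cells. Of 47 tested, 44 were negative, 30 were lower at an unadjusted limma p under 0.05 and 25 adjusted over the list alone, with 0 called over all genes by limma or edgeR (median −2.58, camera adjusted p = 6.7e-28, 0.210 with an estimated correlation; 12 lower in the authors' deposited table). Their medians in the knockdown libraries were −2.54, −3.21 and −1.48 against 0.59 and −0.59 in the controls. CSTA, an envelope protease inhibitor, changed by −0.55. Barrier genes had a median of −1.01 in 34 (camera 1.1e-11, 0.285 estimated; 11 lower unadjusted), with KLK5 at −0.98. Wound keratins (−1.12 in 6, camera 0.000249, 0.510 estimated; KRT6A −0.80), immediate early genes (−0.81 in 28, 2.2e-08, 0.210 estimated; 4 lower adjusted over the list alone; HSP90AA1 −0.53), glycolysis genes (−0.76 in 25, 2.1e-05, 0.333 estimated; LDHA −0.20) and cytokine genes (−0.47 in 40, 1.0e-04, 0.361 estimated; S100A9 −0.18) were called downward. The p53 targets (0.37 in 28, 0.000885, 0.210 estimated; CDKN1A −0.08) and interferon genes (0.30 in 47, 0.00308, 0.871 estimated; SAMD9 0.30) were called upward, the latter lost without control B (0.0877) or knockdown replicate 1 (0.805). KRT14, S100A9 and LDHA changed sign under quantile scaling, and CDKN1A under quantile scaling and at the same total. S100A9 and CDKN1A were positive in the authors' deposited table (0.18 and 0.03), by edgeR and without control A.

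Proliferation and replication genes depended on the control. Their medians of −0.26 (camera 0.128; TOP2A 0.11) and −0.11 (0.631; PCNA 0.26) became 0.21 (0.0119) and 0.24, called upward, without control B, and −0.75 (5.9e-11) and −0.46, called downward, without control A. Both lists were also called downward without knockdown replicate 1 and were positive without replicate 3 (0.05 and 0.13), and the proliferation list passed at the same total. Spinous genes (−0.26, camera 0.0927; PERP −0.34) and transcription factors (−0.16, 0.0771; EHF 0.12) passed at the same total and without control B, and the spinous genes also without knockdown replicate 2. Simple keratins (−0.28, 0.129; KRT13 −1.79) passed at the same total and without control B or knockdown replicate 1. The other lists did not pass camera: basal progenitor genes −0.10 (0.21 without control B, called downward without control A or knockdown replicate 2; KRT14 −0.47), TGF-beta and EMT −0.13 (FN1 0.66), SWI/SNF 0.12 with a mean of −0.03 (−0.05 without knockdown replicate 2; SMARCE1 0.57), SUMO 0.05 (SUMO2 0.10), cholesterol −0.06 (0.09 at the same total, called downward without knockdown replicate 1; SCD −0.77), fibroblast 0.37 (−0.12 without knockdown replicate 2; MFAP5 −0.27), melanocyte −0.68 (called without control B; MITF −0.82), immune 0.34 (CD68 −0.27) and endothelial −0.82 with the test upward (EGFL7 0.96). Camera called 2 lists upward and 6 downward, 0 with an estimated correlation (lowest 0.210), and fry 0.

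In differentiated cells with PIAS1 knockdown, PIAS1 went from 602 ± 28.9 to 80.1 ± 30.9 normalised counts (mean ± SD, n = 2 each), below both controls in both libraries. Its log2 change of −2.95 ± 0.35 did not pass over all genes (limma adjusted p = 0.333) and passed without knockdown A or B; the authors' deposited table gives −2.93 with an adjusted p of 1.4e-08. PBRM1 changed by −0.10 (0.917). No gene of 13598 passed limma (lowest adjusted p 0.333; 820 higher and 996 lower at an unadjusted p under 0.05) or edgeR (0; 1849 unadjusted). Without knockdown A limma called 1331 higher and 1742 lower, and without knockdown B 238 and 237. The authors' deposited table calls 187 higher and 171 lower, including CDKN1A (2.16 ± 0.31, limma 0.333) and S100A9 (2.15 ± 0.36, 0.333), which were also called without knockdown A or B. At the same total the median of all genes moved by −0.12.

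Growth and metabolic genes went down as groups after PIAS1 loss in differentiated cells, with 0 members called over all genes by limma or edgeR. All 34 proliferation genes were negative (median −1.59, camera adjusted p = 1.1e-14, 0.569 with an estimated correlation; 25 lower at an unadjusted limma p under 0.05), among them TOP2A (−2.23 ± 0.77, limma 0.352). Replication genes (−1.09 in 39, camera 3.7e-11; PCNA −0.54), basal progenitor genes (−1.10 in 30, 9.6e-09, 6 lower adjusted over the list alone; KRT14 −0.28), cholesterol genes (−0.84 in 30, 3.8e-09; SCD −0.84) and glycolysis genes (−0.91 in 25, 7.3e-10, 4 lower over the list alone; LDHA −0.71) were called downward, each with 0.569 estimated. Transcription factors (0.48 in 30, camera 0.0132, 0.569 estimated), cytokine genes (0.64 in 40, 0.00497, 0.569 estimated), simple keratins (0.71 in 9, 0.0244, 0.575 estimated; KRT13 0.63) and p53 targets (0.40 in 28, 0.0132, 0.569 estimated) were called upward. The first pair lost the call without knockdown B, the second pair without knockdown A. Without knockdown A, SPRR1B, TOP2A, PCNA, FN1 and SCD were called as well.

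Differentiation genes split the PIAS1 libraries of differentiated cells. The cornified envelope list (median 0.49 in 46, camera 0.327; SPRR1B 0.24) was −0.77 and called downward without knockdown B (0.00124), 1.80 and called upward without knockdown A (1.1e-05), called upward without control A, and −0.05 without control B. Barrier genes (−0.03; KLK5 0.47) became −0.66 without knockdown B and 0.47 without knockdown A, both called, and spinous genes (median 0.20 with a mean just below 0; PERP 0.20) were −0.33 and 0.95, both called as well. SPRR1B, PERP and KLK5 changed sign under quantile scaling, and FN1 went from −1.01 to 0.16 in the authors' deposited table. Interferon genes (−0.19 with the test upward, camera 0.639; SAMD9 0.81) were −1.07 and called downward without knockdown A, and 0.98 and called upward without knockdown B (5.2e-12). The remaining lists did not pass: wound keratins 0.71 (called without knockdown A, −0.07 without knockdown B; KRT6A 0.21), TGF-beta −0.66 (4 higher and 5 lower over the list alone), SWI/SNF −0.20 (SMARCA4 −0.15), SUMO −0.04 (0.07 without control B; SUMO2 0.26), immediate early 0.25 (called without control A or knockdown A; HSP90AA1 −0.15), fibroblast −0.71 (MFAP5 −0.40), melanocyte 0.19 (−0.73 without knockdown B; MITF −0.17), immune 0.99 (called without control B; CD68 0.99) and endothelial 1.95 (called without control A; EGFL7 0.24). Camera called 4 lists upward and 5 downward, 0 with an estimated correlation (lowest 0.569), and fry 0.

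In differentiated cells limma called 0 genes for either knockdown, so its calls cannot show whether genes are shared. Log2 changes had Spearman's rho −0.00878 across genes, against 0.706 in undifferentiated cells. At an unadjusted p under 0.05, 15 genes were higher in both (15.0 expected) and 48 lower (31.5 expected, Fisher's exact test odds ratio 1.62, p = 0.00336). For PBRM1 the genes at that unadjusted p are near the number that chance gives. The authors' deposited tables share 1 rise (0.113 expected, exact p = 0.107) and 4 falls (0.420 expected, odds ratio 10.3, exact p = 0.000837), while 5 genes lower after PBRM1 loss were higher after PIAS1 loss.

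The effect of PBRM1 knockdown differed between the states for 690 of 13511 genes (difference of the limma effects, 57 higher and 633 lower in differentiated cells). Cornified envelope genes had a median difference of −6.91, with 38 of 43 lower (camera adjusted p = 1.5e-104), barrier genes −4.74 (25 of 33, 7.3e-50), spinous genes −2.87 (13 of 27, 1.6e-26) and transcription factors −1.93 (18 of 30, 3.5e-25), while replication genes (0.89, 1.4e-09) and proliferation genes (0.89, 4.5e-07) differed the other way. With an estimated correlation in a single edgeR fit only cornified envelope genes, transcription factors and immediate early genes passed (adjusted p = 0.0394 each), and no list with the hairpin as a block (lowest 0.240). KRT23 (−6.33), OVOL1 (−6.44), KRTDAP (−5.78) and ZNF750 (−5.08) are among the named genes that differed. A stricter test with a t reference called 1 higher (TICAM2, 4.61, chosen after its values were seen) and 225 lower. The edgeR fit called 3 higher (DDX60 1.75, MEST 1.79 and XAF1 2.83, also chosen afterwards) and 177 lower, and 45 and 634 with the hairpin as a block. Leaving out 1 library gave 272 (differentiated control A) to 1180 (differentiated knockdown replicate 1) genes, and 380, 389 and 1155 without undifferentiated control A, control B and knockdown replicate 2.

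The effect of PIAS1 knockdown differed between the states for 936 of 13120 genes (250 higher and 686 lower in differentiated cells). Barrier genes had a median difference of −3.81 (20 of 34 lower, camera adjusted p = 7.3e-27), cornified envelope genes −3.60 (16 of 43, 3.2e-17), spinous genes −2.43 (12 of 25, 1.4e-14), and replication genes 1.66 (14 of 39 higher, 1.2e-18). No list passed with an estimated correlation in a single edgeR fit, without or with the hairpin as a block (lowest 0.228 and 0.103). NOTCH3 (−4.70), KLK6 (−4.65), KLK7 (−4.68), OVOL1 (−5.30) and PCNA (1.79) are among the named genes that differed. With a t reference 67 genes passed (66 lower and PCNA higher), and the edgeR fit called 4, all lower and chosen after their values were seen: C2orf54 (−7.32), METRNL (−3.80), CREBRF and RNF223 (−5.86). The same fit with the hairpin as a block called 87 higher and 318 lower, if the hairpins of both states are the same: they carry letters in one table and numbers in the other and were matched by the sample labels. Leaving out 1 library gave 204 (undifferentiated control A) to 3464 (undifferentiated knockdown A) genes, 264 without undifferentiated control B, 225 and 318 without differentiated control A and B, and 1862 to 2364 without any other knockdown library.

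PBRM1 and PIAS1 regions, called per library by the authors, overlapped widely in undifferentiated cells. PBRM1 had 15139 regions found in both replicates (overlap of at least 1 bp; 31.6 Mb) and PIAS1 20120 (20.7 Mb). Of 20054 PIAS1 regions on the main chromosomes, 9336 (46.6%) overlapped a PBRM1 region, against 1.86% after shuffling and 12.6% after shuffling that kept the distance class to gene ends (permutation p = 0.0099, the smallest that 100 shuffles can give). BRD7 had 10789 regions (18.9 Mb), of which 50.7% overlapped PBRM1 (1.91% and 10.6% shuffled, permutation p = 0.0099) and 39.5% PIAS1 (1.80% and 8.33%, permutation p = 0.0099). At −log10 q of at least 5 the shares of PIAS1 and BRD7 regions that overlapped PBRM1 were 11.9 and 12.8%, and at a reciprocal overlap of 50% they were 22.4 and 30.2%. The shuffled shares above belong to the full sets at 1 bp. They are no reference for these stricter shares, for which no shuffled value is given here. Of the PBRM1 regions, 24.3% overlapped both PIAS1 and BRD7, 35.2% only PIAS1, 11.3% only BRD7 and 29.2% neither. Among the authors' scores the highest PBRM1 regions were at SPON2 (chromosome 4, 1171541 to 1172591 in hg38, −log10 q 36.2), on chromosome 8 at 98166800 to 98168701 (30.9) and on chromosome 6 at 4459824 to 4461492 (29.2). For PIAS1 they were on chromosome 16 at 2867863 to 2868687 (84.0), at SKA3 on chromosome 13 (83.3) and at FLYWCH2 on chromosome 16 (77.9), and for BRD7 at JMJD7 on chromosome 15 (18.0), on chromosome 12 at 31369291 to 31370686 (17.0) and at ZNF430 on chromosome 19 (16.7).

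**Figure D4:**
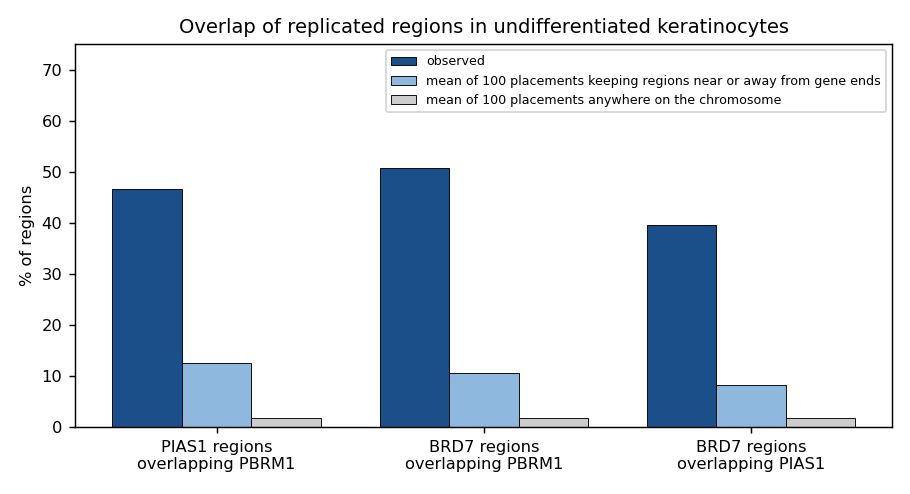
Percent of replicated regions of 1 protein that overlap those of another in undifferentiated cells, measured and after shuffling. Of PIAS1 regions 46.6% overlap PBRM1, against 1.86% and 12.6% under the 2 kinds of shuffle.

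Fewer regions were listed in differentiated cells. PBRM1 had 6714 (13.3 Mb), and 35.2% of the undifferentiated regions overlapped one of them, while 80.9% of the differentiated regions overlapped an undifferentiated one. The highest were at TRAK1 (10.4) and ZBTB47 (9.96) on chromosome 3 and at CHD9NB on chromosome 16 (9.86). PIAS1 lists held 14 and 40 regions, with 9 in both replicates, 8 of these on the main chromosomes. In tested coding genes lay 4, at KRT5 (chromosome 12, 52514608 to 52514906 and 52517613 to 52517736), KRT6A (52487219 to 52487725) and S100A2 on chromosome 1. The others on the main chromosomes lay in no tested gene. They were on chromosome 1 at 630287 to 630342 (the highest score, −log10 q 3.53), 124579475 to 124579533 and 143246963 to 143247093, and on chromosome 16 at 33336759 to 33336856. Read depth and input are not given for these libraries, so fewer regions need not mean less binding. At −log10 q of at least 5, 3496 PBRM1 and 2920 PIAS1 regions stayed in undifferentiated cells and 123 and 0 in differentiated cells.

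Some named regulators had regions of both PBRM1 and PIAS1 within 5 kb of a gene end in undifferentiated cells. So did 8306 of 13319 tested genes, so having both is common and does not set these regulators apart. At OVOL1 (chromosome 11) PBRM1 lay at 65786113 to 65788520 and PIAS1 at 65786370 to 65787808, at GRHL1 (chromosome 2) at 9950675 to 9953088 and 9950895 to 9951909, and at ZNF750 (chromosome 17) at 82839963 to 82840961 and 82836068 to 82836553. ELF3 (chromosome 1, PBRM1 202007483 to 202008196, PIAS1 202007956 to 202008576) and DLL1 (chromosome 6, 170287377 to 170291833 and 170289049 to 170291801) also had both. CDKN1A (chromosome 6) had PBRM1 at 36677759 to 36680290, PIAS1 at 36676297 to 36680850 and BRD7 at 36676333 to 36679284. PBRM1 and PIAS1 each had both proteins at their own end, at 52685181 to 52687677 and 52685394 to 52686421 on chromosome 3 and at 68053852 to 68056714 and 68053935 to 68054809 on chromosome 15. Of 115 named genes, 74 had a PBRM1 region and 70 a PIAS1 region in undifferentiated cells (80.0 and 67.9% of all tested genes had one). A BRD7 region lay near 23 (31.5% of all tested genes). In differentiated cells 31 had a PBRM1 region (37.4% of all tested genes) and 1, KRT6A, a PIAS1 region.

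By list, PBRM1 regions were rare near envelope genes. In undifferentiated cells 28 of 30 transcription factors and 28 of 30 basal progenitor genes had one, and the difference from the 80.0% of all tested genes did not pass (adjusted p = 0.220 each, Fisher's exact test over the lists). Fewer had one among the cornified envelope genes (6 of 43, adjusted p = 1.5e-18: ASPRV1, CALML5, CDSN, EVPL, IVL and PPL), barrier genes (14 of 32, 8.5e-05), interferon genes (26 of 47, 0.00119), spinous genes (13 of 27, 0.00178) and cytokine genes (23 of 38, 0.0383). PIAS1 had regions near 11 of 44 envelope genes (2.6e-07) and 7 of 33 barrier genes (1.2e-06), against 67.9% of all tested genes. BRD7 had them near 24 of 30 basal progenitor genes against 31.5% (1.2e-06), 15 of 26 TGF-beta and EMT genes (0.0383), 2 of 43 envelope genes (0.000265) and 2 of 39 replication genes (0.000936; POLE2 and RFC4, chosen after their values were seen). In differentiated cells PBRM1 had regions near 3 of 46 envelope genes against 37.4% (3.3e-05), 3 of 33 barrier genes (0.00308) and 5 of 34 proliferation genes (0.0383). Many envelope genes lie in 1 cluster on chromosome 1: there 1 of 32 had a PBRM1 region, and elsewhere 5 of 11.

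**Figure D5:**
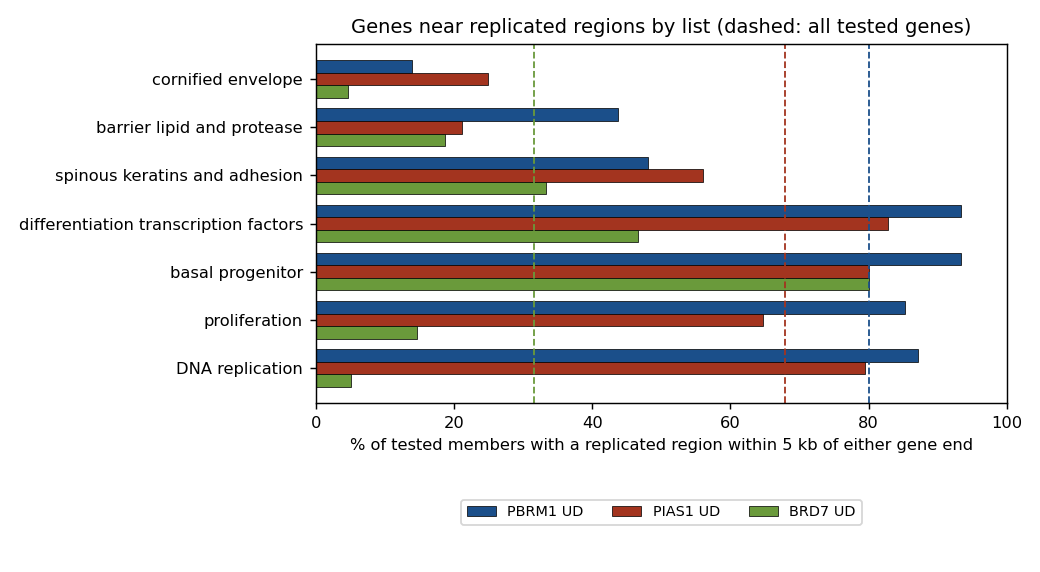
Percent of tested genes of each list with a replicated region within 5 kb of a gene end, by protein in undifferentiated cells; dashed lines give all tested genes. For PBRM1, 6 of 43 cornified envelope genes have one, against 80.0% of all.

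Genes that rose after PBRM1 knockdown had a PBRM1 region less often than uncalled genes (242 of 358, 67.6%, against 80.3%, Fisher's exact test odds ratio 0.512, p = 3.0e-08, adjusted p = 4.8e-07; 0.484 within expression quartiles). The same genes also had a PIAS1 region less often (57.8% against 68.1%, odds ratio 0.642, exact test adjusted p = 0.000307) and a BRD7 region less often (24.9% against 31.6%, 0.715, adjusted p = 0.0231), so the lower share is not particular to PBRM1. For PBRM1 regions at −log10 q of at least 5 the odds ratio was 0.815 and the difference no longer passed (exact p = 0.152). Those that fell had one in 66 of 74 cases (odds ratio 2.03, exact p = 0.0564; 3.35 counting regions within the gene as well, 1.08 at −log10 q of at least 5). After PIAS1 knockdown, 503 of 714 rising genes (70.4% against 67.6%, odds ratio 1.14, exact p = 0.118) and 282 of 399 falling genes (odds ratio 1.15, exact p = 0.211) had a PIAS1 region, and within expression quartiles the odds ratios were 0.865 and 0.960. At 50 kb the odds ratio of the rising genes was 1.5 and passed (exact p = 0.00273), and with the authors' deposited calls it was 0.798 within expression quartiles (Cochran-Mantel-Haenszel p = 4.9e-05), so its direction depends on these choices.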

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

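The tests of the PIAS1 region lists and of the PBRM1 effect in and between the states were chosen only after the result was seen. Those of the regions near envelope genes were chosen before, apart from the direct comparison with the transcription factors, which was not planned. They count regions within 5 kb of either gene end, however, and that distance was chosen only after the result was seen.

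The effect of a knockdown differed between differentiated and undifferentiated cells for 31 named genes with PBRM1 and 30 with PIAS1 (54 different genes, 7 of them with both), and for 10 and 12 lists (14 different ones). Of the 61 gene results 27 also pass with a t reference. Values are the effect in differentiated cells minus that in undifferentiated cells on the log2 scale. The test of the difference singled these out, but the genes were taken from the named genes. Many of those were named for large called changes in undifferentiated cells. That choice by itself favours a difference opposite to the undifferentiated change.

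For PBRM1 the named genes past both forms of the test were LCE2B (−9.75), SPRR2G (−8.58), ARG1 (−7.60), S100P (−6.96), KRT78 (−6.83), ALOX12B (−6.51), OVOL1 (−6.44), RNF222 (−6.42), KRT23 (−6.33), SDR9C7 (−6.30), EEF1A2 (−5.98), EGR3 (−5.97), KRTDAP (−5.78), PI3 (−5.12), ZNF750 (−5.08), KRT6B (−3.90), KRT16 (−3.72), GRHL1 (−3.28), CHAC1 (−3.18), ID2 (−3.09) and CD68 (−1.45). ARG1 and EEF1A2 rest on 3 reads over the undifferentiated controls, so their values are no exact sizes. Past the normal form alone were HIST2H2AA4 (−13.75, with a near-identical copy and fitted over undifferentiated controls at 0, so not an exact size; the sum over both copies changed by 1.38 in undifferentiated and −0.32 in differentiated cells), KRT13 (−4.22), S100A9 (−3.54), KLK5 (−3.25), SESN2 (−1.93), KRT6A (−1.73), PERP (−1.39), HERC5 (1.26), PCNA (1.35) and COL5A2 (1.40).

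For PIAS1 those past both forms were NOTCH3 (−4.70), KLK7 (−4.68), KLK6 (−4.65), WNT10A (−4.53), KLK5 (−3.09) and PCNA (1.79). Past the normal form alone were PLA2G4B (−9.11, also over undifferentiated controls at 0 and not an exact size), SLC5A1 (−7.17), PLA2G2F (−6.87), TMPRSS11E (−5.50), ELF3 (−5.43), OVOL1 (−5.30), SULT2B1 (−4.52), ZNF750 (−4.27), SPRR2D (−3.81), TRIM63 (−3.80, over 2 such control reads and no exact size either), EGR3 (−3.62), MMP9 (−3.60), SPRR1B (−3.60), MMP10 (−3.45), S100A9 (−3.42), CLDN4 (−2.52), KRT16 (−2.50), S100A4 (−2.28), ISG20 (−1.90), MSMO1 (−1.89), SC5D (−1.43), SLC2A1 (−1.33), ELAVL2 (2.32) and XRCC2 (2.52).

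By list, the median differences for PBRM1 were −6.91 for cornified envelope, −4.74 for barrier, −3.46 for wound keratins, −2.87 for spinous, −1.93 for transcription factors, −1.14 for cytokine, −1.13 for immediate early, 0.59 for interferon and 0.89 for both proliferation and replication genes. For PIAS1 they were −3.81 for barrier, −3.60 for cornified envelope, −2.43 for spinous, −1.36 for cytokine, −1.28 for transcription factors, −1 for cholesterol, −0.94 for basal progenitor, −0.75 for glycolysis, −0.63 for TGF-beta and EMT, 0.73 for interferon, 1.66 for replication and 1.71 for proliferation genes. These lists were called by camera with a preset correlation. With an estimated correlation, in an edgeR fit over both tables that was chosen only after the result was seen, 3 lists passed for PBRM1 (0 with the hairpin as a block) and 0 for PIAS1 with or without the block.

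The first pattern weighed is that cornified envelope genes were higher after PBRM1 loss in undifferentiated cells and lower in differentiated cells. In differentiated cells 0 genes were called by limma (716 unadjusted, near the number that chance gives) or edgeR (1193 unadjusted). There the list is lost with an estimated correlation (0.210). At the same total per library the medians of the list were 4.32 and −2.43. The normalised totals were already close (28.9 to 31.4 M in undifferentiated and 25.5 to 31.0 M in differentiated cells). This scaling could therefore hardly move the medians, and it does not decide on the scaling of the libraries. A single library is argued against: with 1 library left out the undifferentiated median was at least 3.85 and the differentiated one at most −2.00. Reads shared between near-identical family members are argued against in undifferentiated cells by a median of 4.41 over the 19 members outside the SPRR and LCE families. In differentiated cells they stay open for the size of the fall, since the 21 such members had a median of −0.996 (18 negative) against −2.58 for the list. A role of PBRM1 that differs between the states is a candidate explanation and stays untested. Separate processing that acts alike on all libraries of a table is argued against, since each median compares knockdowns with controls of the same table. Processing that differed between libraries within a table stays open.

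The second is that the PIAS1 lists hold 14 and 40 regions in differentiated cells against 25571 and 26018 in undifferentiated cells. The lists do not reach down to the same score. The lowest −log10 q was higher in both lists of differentiated cells than in those of undifferentiated cells. At a shared −log10 q of at least 5 the lists hold 2 and 12 regions against 8354 and 9270. Unlike lowest scores are thus argued against as the whole cause. Less PIAS1 mRNA is argued against, because PIAS1 rose by 0.52 in the controls. Of the regions of differentiated replicate 2 in a tested gene, 91.3% lie in the 5% of genes with the highest level (21 of 23, against 7.32 and 7.49% in the lists of undifferentiated cells). However, 32 and 30 of its 40 regions, and 9 of the 14 of replicate 1, overlap a region of undifferentiated replicates 1 and 2, so signal at very abundant transcripts and signal at PIAS1 sites cannot be told apart. Whether PIAS1 leaves chromatin stays open: 6 undifferentiated regions overlap a differentiated one, but depth and enrichment of these libraries are not given in the sources used here.

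The third is that PBRM1 regions in undifferentiated cells lie near 28 of 30 differentiation transcription factors but 6 of 43 cornified envelope genes (Fisher's exact test odds ratio 77.1, p = 4.4e-12). Setting 1 list against another was not planned, so this p-value adds no support beyond the test of each list. A low level of the envelope genes stays open, although the odds ratio was 0.0224 within expression quartiles. Those quartiles used the mean over controls and knockdowns, and the knockdowns raise these genes, so they do not match the level in unperturbed cells. Short genes are argued against as the whole cause by an odds ratio of 0.0437 within length quartiles. The chromosome 1 cluster stays open, since 45.5% of the members elsewhere (5 of 11) had a region. The difference of the share near the factors from the 80.0% of all tested genes did not pass (exact test, adjusted p = 0.220).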

How the results depend on the processing

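The tests with edgeR on recovered reads, the same total per library, the t reference, crossed hairpin letters, the direction of differentiation, and for genes with regions 5 kb from either end, gene span plus 5 kb and the authors' deposited adjusted p were chosen only after the result was seen; the others were planned.

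The number of changed genes depends on the processing. For PBRM1 in undifferentiated cells (434) it was 2286 by the authors' deposited adjusted p, 247 by edgeR, 26 at an adjusted p of 0.01 and 3 to 1793 with 1 library left out. For PBRM1 in differentiated cells (0 by limma, 716 unadjusted, near the number that chance gives, 0 by edgeR) it was 81 by the authors' deposited adjusted p and 1 at the same total. For PIAS1 in undifferentiated cells (1119) it was 3208 by the authors' deposited adjusted p, 1765 at the same total, 2386 with the hairpin letter as a replicate block, 0 at an adjusted p of 0.01 and 0 to 7427 with 1 library left out. For PIAS1 in differentiated cells (0 by limma, 1816 unadjusted, 0 by edgeR) it was 358 by the authors' deposited adjusted p and 0 to 3073 with 1 library left out. The letter block does not change the 0 there, with letters matched or crossed, and letters name different hairpins. Leaving out 1 of 2 libraries leaves a lone sample, which is assumed to vary like the other group. In undifferentiated cells the controls lay closer together than the knockdowns. Their chi-square of read counts per degree of freedom was 7.29 against 120 to 158 for PBRM1, and 16.2 against 292 for PIAS1. Without 1 control the spread of a gene thus comes from the knockdowns alone, and without 1 PIAS1 knockdown from the controls alone. Fewer libraries also change the estimated spread, so counts can grow. Otherwise the cause was not tested.

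Camera called 15, 8, 12 and 9 lists for PBRM1 undifferentiated and differentiated and PIAS1 undifferentiated and differentiated. With an estimated correlation it called 0 in each, and fry called 7, 0, 0 and 0. With 1 library left out the 8 lists of PBRM1 in differentiated cells became 8 to 13. The cause was not tested.

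The 166 genes shared in undifferentiated cells became 0 at an adjusted p of 0.01 (PIAS1 has no call there), 2104 at an unadjusted p under 0.05 and 0 to 546 with 1 library left out. In differentiated cells, where neither knockdown has a limma call, 0 became 63 at an unadjusted p under 0.05. The state difference of PBRM1 (690) became 226 with a t reference, 180 in 1 edgeR fit and 272 to 1180 with 1 library left out. That of PIAS1 (936) became 67, 4, 405 in the edgeR fit with hairpin (matched by label) as a block, and 204 to 3464. Of the 331 PBRM1 calls also called between the states 89.7% went with differentiation, and of 24 such calls at an adjusted p of 0.01, 100%. The cause was not tested.

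At −log10 q of at least 5 the replicated PBRM1 regions went from 15139 to 3496 in undifferentiated and from 6714 to 123 in differentiated cells, and the PIAS1 regions from 20120 to 2920 and from 9 to 0. A reciprocal overlap of 50% left 3944 PBRM1 regions in differentiated cells. A single replicate gave 8008 to 16989 of these, and 14 to 40 for PIAS1. The odds ratio of a PBRM1 region near genes that rose (0.512) was 0.815 at −log10 q of at least 5, where the call was lost. Near genes that fell (2.03) it passed the threshold at 1 kb (2.02), within the gene span plus 5 kb (3.35) and with the authors' deposited calls (1.59), but was 1.08 at −log10 q of at least 5, 1.17 at 50 kb, 1.24 without replicate 2 of the regions and 1.56 within expression quartiles. For PIAS1 the odds ratio of rising genes (1.14) was 1.5 at 50 kb, where it passed the threshold, 0.865 within expression quartiles, and 0.798 within quartiles with the authors' deposited calls, where it passed the other way; that of falling genes (1.15) was 0.960 within quartiles. The cause was not tested.

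For the named genes, alternatives kept direction and side of the threshold in 485 cases, and lost the call in 155, for PBRM1 undifferentiated; 655 and 157 for PIAS1 undifferentiated. In differentiated cells 291 cases each (PBRM1 and PIAS1) kept both, 1 and 14 gained a call and 20 and 17 moved beyond the spread. For lists 105 and 102 cases kept both, and 14 and 3 lost the call, for PBRM1 and PIAS1 undifferentiated; 93 and 85 kept both in differentiated cells, where 2 and 4 lost the call, 17 and 10 gained one and 20 and 11 moved. A filter on fold enrichment was not run, since that column holds impossible values, and regions near changed genes in differentiated cells were not tested on limma calls, of which there are 0; with the authors' deposited calls a PBRM1 region lay near 6 of 16 higher and 16 of 60 lower genes (odds ratio of the latter 0.608, exact p = 0.108). With the simulated spread, a change of 1 on the log2 scale is found in 0 to 19.8% of genes.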

Other observations

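Of these values, the tests of groups that do not overlap and of regions near gene ends were chosen only after the result was seen.

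Across genes, which are not independent replicates, the log2 changes of PBRM1 knockdown in undifferentiated and differentiated cells had Spearman's rho 0.165 and Pearson's r −0.058, against 0.569 (Spearman) for PIAS1. With the change of the controls on differentiation, rho was 0.308 and −0.19 for PBRM1 in undifferentiated and differentiated cells and 0.453 and 0.311 for PIAS1.

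Genes whose knockdown libraries all lay beyond both controls made up 49.8% and 23.4% of tested genes for PBRM1 in undifferentiated and differentiated cells, where chance gives 20%. For PIAS1 they made up 66.3% and 50.9%, where chance gives 33.3%.

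Regions near gene ends made up 69.7% of PBRM1 regions in undifferentiated cells, 65.7% in differentiated cells, 48.9% of PIAS1 and 38.6% of BRD7 regions in undifferentiated cells, against 10.1% of the span of the main chromosomes. BRD7 regions of undifferentiated cells overlapped PBRM1 regions of differentiated cells in 33.6% of cases.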
